A study of Macaca mulatta with 440 samples.

How the data were processed

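Blood was drawn from 45 female rhesus macaques in each of 2 study phases, and 5 populations of blood mononuclear cells were sorted from each draw by surface markers: helper T cells (CD3 and CD4 positive, CD8 negative), cytotoxic T cells (CD3 and CD8 positive, CD4 negative), monocytes (HLA-DR and CD14 positive, CD3 and CD20 negative), natural killer cells (CD16 positive, CD3, CD20 and HLA-DR negative) and B cells (CD20 and HLA-DR positive, CD3 negative). Per the labels' protocols, 12 to 20 mL of blood was taken, 200 ng of RNA per library went through polyA selection and 13 cycles of amplification, and 10 to 12 libraries shared a lane of single-end sequencing with reads of 100 bp from fragments with a median near 350 bp. The animals lived in 9 study groups of 5 per phase and every animal moved to a new group between the phases. No 2 animals shared a study group in both phases. Phase 1 was sampled in 2013 and phase 2 in 2014. The social rank of the animals was not used here.

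Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.2.7, aligned them with STAR, counted them per gene with HTSeq 0.6.1 and used limma. The genome build and annotation are not given in the sources used here. The deposited count table holds raw read counts for 16049 gene symbols in 440 libraries, and 105 of the genes had no count in any library. The deposited residual tables, 1 per cell type and 1 for all 5 types, hold log2 values that are residuals of a model not described in the sources used here. The residuals of each single cell type were centred on the study groups: their median absolute difference between the phases lay between 0.000917 and 0.00312 over the 5 tables, against 0.492 to 0.797 for log2 CPM of the same libraries. They therefore hold no phase effect, and all tests started from the counts. Gene symbols were used as deposited; 14840 of the 16049 were found in the gene name tables at hand, and no coordinates are given.

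Every library was assigned to a cell type, phase, animal, study group and sampling date from its labels, and 0 columns of the tables stayed without a sample. The animal numbers pair libraries across phases and cell types. CPM values are read counts scaled by the library total and, unless they are called unscaled, by edgeR's TMM factor (the trimmed mean of M values). Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0; checks, correlations and plots used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The main test was edgeR's quasi-likelihood F test with robust dispersions on genes kept by filterByExpr, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05.

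Cell types were compared in a single fit of all 440 libraries, with cell type by phase as the groups and the animal as a block, and a gene was called where it also differed at least 2-fold. A gene high in a type was called higher there than in each of the other 4 types. The phases were compared within each cell type over animals with a library in both phases, with the animal as a block. The difference of the phase effect between cell types was a joint test in the fit of all libraries. Differences among the 9 study groups, among sampling dates within study groups, and by the study group of the other phase were joint F tests within each cell type and phase. Differences among animals were a joint F test over both phases with phase as a covariate. The pairing was checked by correlating each library's deviations from the phase mean with those of the same animal and of other animals in the other phase, with 100000 shuffles of the animal labels as the permutation test. Relations of named genes between phases were given as Pearson's r and Spearman's rho with permutation p-values; where the animals fell into separate levels (a gap of at least 2 on the log2 scale) r was taken within each level.

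Lists of genes were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternative settings. They were markers of B cells, monocytes, natural killer cells, T cells, helper T cells and cytotoxic T cells; markers of neutrophils, platelets, erythroid cells, plasma cells and dendritic cells; and genes of the interferon response, NF-kB and inflammation, glucocorticoid response, immediate early response, heat shock, circadian clock, cell cycle, cytotoxic granules, class II antigen presentation, oxidative phosphorylation, chemokine receptors and homing, and ribosomal proteins. Each list was tested in the phase comparison with limma's camera at a preset correlation of 0.01, adjusted over the 105 combinations of list and cell type tested, and again with the correlation estimated from the data and with fry.

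Named genes followed the fixed rule. For each cell type these were the 5 genes high in it with the largest smallest fold change and an average log2 CPM of at least 4. For the phases they were the 4 higher and 4 lower genes with the largest fold change, an average log2 CPM of at least 3 and the same direction in at least 75% of animals. The 5 smallest p-values were taken for the difference between types, 2 per phase and type for study groups and 4 per type for animals, and from each list the 2 to 4 members with the smallest p-value. Some genes were named outside this rule, among them members that moved against their list, gate genes, and genes of the other observations.

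Totals ranged from 218027 to 19903858 counted reads per library (median 7277783). At the median total, a gene at 1 CPM had about 7.28 reads, so genes below that level carried mainly counting error. For duplicates, libraries of each cell type and phase were compared by a chi-square test over genes with mean counts of at least 20. No such pair matched within sampling noise, and pairs across types or phases were not compared. The steps were tested on simulated data built from these libraries. The simulated libraries shared no effects of study group, date or animal beyond those set, and few of the genes were changed. The shares recovered and false therefore need not hold for the real comparisons. For the phase comparison in natural killer cells, 61% of genes changed 1.25-fold and 99% of those changed 2-fold were recovered over 9706 genes, and 8.05% of calls were false. For animals (9706 genes, a log2 SD of 0.5 between animals) 84% were recovered and 20.4% of calls were false. For study groups in natural killer phase 1 (10100 genes, 1 group at 2-fold) 56% were recovered and 13.2% of edgeR calls and 5.83% of limma-voom calls were false; for the other phase's study group 47.5% were recovered, with 15.9% and 6.76% false. For B cells against monocytes (2000 genes) 97% of genes changed 2.5-fold and 100% of those changed 4-fold were recovered with 0 false calls.

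The alternatives were other size factors, no or a stricter filter on low counts, the genes of the authors' residual tables, no block, non-robust dispersions, limma-voom, DESeq2, leaving out libraries with the lowest totals or each study group or replicate in turn, and the log10 total or the level of the marker lists of the other gates as covariates. Added after the data had been seen were leaving out 7 libraries whose genes spoke against their label, leaving out the shallowest libraries below a fixed total, thinning the counts of each animal's pair to the lower total, the level of the immediate early and NF-kB lists as a covariate, and the authors' residuals in the comparison of animals. The 7 libraries were B phase 2 replicate 23, cytotoxic T phase 2 replicate 7, helper T phase 1 replicates 34 and 36, helper T phase 2 replicates 7 and 42, and natural killer phase 2 replicate 22; all were kept in the main tests. The residual tables were left out of the phase comparison because of their centring.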

Results

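RNA was sequenced from 5 sorted populations of blood mononuclear cells of 45 female rhesus macaques, each sampled in 2 phases of a study of social environment and immune gene expression. The 440 libraries formed 10 groups of cell type by phase: helper T cells (45 libraries in phase 1 and 44 in phase 2), cytotoxic T cells (45 and 44), natural killer cells (45 and 43), B cells (44 and 42) and monocytes (45 and 43). All 5 types were present for 82 of the 90 blood draws, and 42 to 44 animals per type had a library in both phases. Library totals ran from 218027 to 19903858 counted reads with a median of 7277783. The median total was 4610813 reads in phase 1 and 8685800 in phase 2. The ratio of phase 2 to phase 1 medians was 2.75 in monocytes, 2.29 in natural killer cells, 2.16 in B cells, 1.14 in helper T cells and 0.851 in cytotoxic T cells. No 2 libraries of the same cell type and phase matched within sampling noise, so each was counted as a separate sample. Values after ± are standard errors for log2 fold changes and SD for CPM (read counts relative to the library total); intervals and floors cover counting error only.

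The first comparison asked which genes set the 5 sorted types apart. Helper T cells were set apart by CD40LG, the ligand through which they engage CD40 on B cells, at 104 ± 46.8 CPM (n = 89) against 4.26 ± 5.92 in cytotoxic T cells. That was a log2 difference of 4.74 ± 0.11 to the next highest type. TSHZ2, a zinc-finger transcription factor, exceeded its next highest type by 3.70 ± 0.12, and EYA4, a transcriptional coactivator, by 3.34 ± 0.12. DOCK1, an exchange factor for Rac, exceeded it by 3.18 ± 0.10 and GIPC2, a PDZ-domain protein, by 3.82 ± 0.11. CD8B, the beta chain of the CD8 coreceptor, marked cytotoxic T cells at 248 ± 95.8 CPM (n = 89), 5.89 ± 0.14 above natural killer cells. Other leading cytotoxic T genes were LAG3, an inhibitory receptor for class II molecules (2.63 ± 0.10 above helper T cells), the granule protease GZMM (2.45 ± 0.10) and PERP, a membrane protein induced by p53 (2.31 ± 0.10), both also next highest in helper T cells. PTMS, parathymosin, lay 2.39 ± 0.10 above monocytes.

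Natural killer cells were set apart by 2 enzymes of retinoid and steroid synthesis. ALDH1A3, which makes retinoic acid, stood at 21.7 ± 13.4 CPM (n = 88) against 0.329 ± 1.23 in cytotoxic T cells (6.34 ± 0.13 on the log2 scale). CYP11A1, which cleaves the cholesterol side chain, lay 4.37 ± 0.14 above its next type. RNF165, a RING finger protein (4.68 ± 0.10), the kinase NUAK1 (4.61 ± 0.11) and the immune cell adaptor CLNK (4.39 ± 0.11) completed their leading genes. B cells held MS4A1, which encodes the gate marker CD20, at 1330 ± 503 CPM (n = 86), 7.45 ± 0.17 above monocytes. SOX5, a transcription factor (7.42 ± 0.12), DENND5B, an exchange factor for Rab proteins (7.39 ± 0.13), and TNFRSF13B, a receptor for the B cell survival factors BAFF and APRIL (7.38 ± 0.12), followed. Monocytes held FN1, fibronectin, at 5362 ± 2687 CPM (n = 88), 7.10 ± 0.17 above B cells. They held CD163, the scavenger receptor for haemoglobin, at 1618 ± 1000 CPM (6.88 ± 0.16). FMN1, a formin (6.82 ± 0.17), SERPINB10, a serine protease inhibitor (6.74 ± 0.11), and RNASE3, best known from eosinophil granules (6.73 ± 0.16), were the other 3. The adjusted p-value against the nearest type was at most 5.68e-74 for each of these genes.

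Of the 11880 genes tested, 979 separated helper from cytotoxic T cells, the fewest of any pair (506 higher in helper and 473 in cytotoxic T cells). The most, 5294, separated helper T cells from monocytes. Natural killer cells differed from cytotoxic T cells in 1942 genes and from helper T cells in 2611. B cells differed from helper T cells in 3296, from cytotoxic T cells in 3264 and from natural killer cells in 3497. Monocytes differed from cytotoxic T cells in 5195 genes, from natural killer cells in 5097 and from B cells in 4779. Genes higher in a type than in all other 4 numbered 1426 in monocytes, 609 in B cells, 244 in natural killer cells, 186 in helper T cells and 54 in cytotoxic T cells. Among the marker lists, 16 of 17 B cell markers and 16 of 16 monocyte markers were high in their own type, against 9 of 11 helper T, 7 of 13 natural killer and 3 of 11 cytotoxic T markers. Of the T cell markers, 7 of 14 were higher in both T gates than in the other 3 types. A minimum of 2 on the log2 scale in place of 1 lowered each of the counts by over 1.5 times. With no filter on low counts 110 genes were high in cytotoxic T cells.

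**Figure D1:**
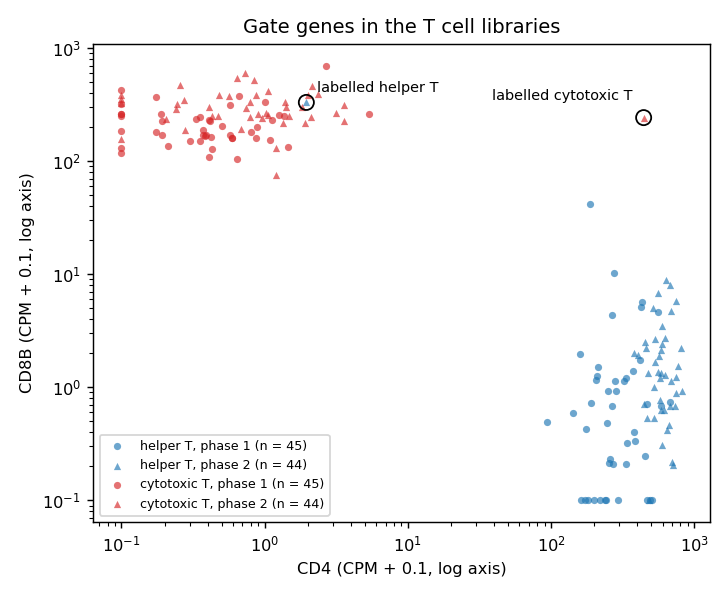
CD4 against CD8B (unscaled CPM, log axes) in the 178 helper T and cytotoxic T libraries, each point a library. The circled libraries are the phase 2 pair of replicate 7, that labelled helper T at 330 CPM of CD8B and that labelled cytotoxic T at 443 CPM of CD4.

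Some libraries carried genes of another gate. In the phase 2 draw of replicate 7, the library labelled helper T held CD8B at 330 CPM and CD4 at 1.86 CPM. The library labelled cytotoxic T held both CD4 (443 CPM) and CD8B (242 CPM), all unscaled. Helper T phase 1 replicate 34, from the same animal, held CD8B at 41.8 CPM. Helper T phase 1 replicate 36 and phase 2 replicate 42 lay nearer to the median cytotoxic T profile than to their own (r across genes 0.924 against 0.917 and 0.945 against 0.941). B phase 2 replicate 23 carried T cell markers at a mean log2 CPM of 6.71 against a median of 1.97 over B libraries. Natural killer phase 2 replicate 22 held CLEC12A at 89.2 CPM, although its animal was among the 19 whose cytotoxic T libraries held at most 1.23 CPM. Leaving out these 7 libraries and the shallowest moved no count of the cell type comparison by over 1.5 times.

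The second comparison set phase 2 against phase 1 within each cell type. In helper T cells CX3CR1, the fractalkine receptor, rose from 38.3 ± 44.4 to 281 ± 206 CPM (3.29 ± 0.19 on the log2 scale, higher in 44 of 44 animals, adjusted p = 2.92e-20). TNFAIP8L2 rose by 3.09 ± 0.16 and is known to restrain T cell receptor and Toll-like receptor signalling. The DNA repair glycosylase SMUG1 rose by 2.62 ± 0.18, and both genes rose in 44 of 44 animals. NR4A3, an orphan nuclear receptor induced within minutes of stimulation, changed by -5.38 ± 0.37 and the stress-induced transcription factor ATF3 by -4.50 ± 0.31, both lower in 43 of 44 animals. TP53INP2, a protein of autophagy, changed by -4.67 ± 0.27 (43 of 44 animals) and RRAD, a small GTPase, by -4.40 ± 0.40 (41 of 44). In cytotoxic T cells TNFAIP8L2 rose by 3.36 ± 0.17 and CX3CR1 by 2.93 ± 0.14. The type I interferon receptor chain IFNAR1 rose by 2.71 ± 0.21 and ACADM, an enzyme of fatty acid oxidation, by 2.53 ± 0.19, all 4 genes in 44 of 44 animals. NXPH4, a neurexophilin, changed by -9.15 ± 0.23, RGS16, a regulator of G protein signalling, by -6.49 ± 0.22 and RRAD by -6.37 ± 0.35, each lower in 44 of 44 animals. C1QL2, a C1q-like secreted protein, went from 6940 reads over the phase 1 libraries to 2 over those of phase 2. That was 3137-fold lower with a 95% counting interval of 868 to 25910.

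Natural killer cells showed rises of TNFAIP8L2 (3.32 ± 0.18), the lymphocyte GTPase GIMAP1 (2.64 ± 0.17), the membrane protein TMEM204 (2.54 ± 0.19) and the chaperonin-like MKKS (2.40 ± 0.19), each in 43 of 43 animals. LMNA, the nuclear lamin A/C, changed by -5.68 ± 0.25 (43 of 43 animals), and RGS16 by -5.51 ± 0.34 and RRAD by -5.14 ± 0.38 (42 of 43 each). FOSB, a subunit of AP-1, changed by -5.11 ± 0.48 (41 of 43), from 3094 ± 1690 to 345 ± 657 CPM. In B cells CX3CR1 rose by 3.50 ± 0.25 (41 of 42 animals). The inhibitory receptor BTLA rose by 2.86 ± 0.18, the adaptor GAPT by 2.78 ± 0.17 and C14orf119 by 2.71 ± 0.15 (42 of 42 each). GJB1, a connexin, fell from 5168 reads to 0 in B cells, at least 3400-fold lower with a floor of 3 reads over the group. C1QL2 changed by -9.80 ± 0.21 (42 of 42) and CYP1B1, an enzyme induced through the aryl hydrocarbon receptor, by -7.61 ± 0.35 (40 of 42). THBS1, thrombospondin 1, fell from 506 ± 941 to 5.55 ± 7.72 CPM (41 of 42). In monocytes CX3CR1 rose by 4.23 ± 0.31 and the formyl peptide receptor FPR3 by 3.83 ± 0.29 (43 of 43 animals each). SHROOM3, an actin-binding protein, rose by 3.19 ± 0.26 and TNFAIP8L2 by 3.18 ± 0.19 (42 of 43 each). CYP1A1 and CYP1B1, the classical targets of the aryl hydrocarbon receptor, changed by -9.91 ± 0.26 and -8.98 ± 0.37 (43 of 43 each). F3, tissue factor, changed by -8.59 ± 0.34 (43 of 43). MET, the hepatocyte growth factor receptor, changed by -8.82 ± 0.26 (41 of 43). All adjusted p-values of these results were at most 1.00e-11.

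Most expressed genes differed between the phases: 4509 rose and 3979 fell of 10443 tested in helper T cells and 4698 and 3959 of 10541 in cytotoxic T cells. The counts were 4167 and 3436 of 9706 in natural killer cells, 4461 and 3879 of 10265 in B cells and 4512 and 3608 of 9809 in monocytes. Changes of at least 2-fold were fewer, with 1104 rises and 928 falls in helper T and 1240 and 1090 in cytotoxic T cells. There were 785 and 603 such changes in natural killer cells, 969 and 996 in B cells and 1733 and 1342 in monocytes. The median log2 change of all genes lay between 0.06 and 0.08 in lymphocytes and at 0.12 in monocytes. The changes given are on the TMM scale without removing it. Of 8817 genes tested in all 5 types, 1976 rose and 1851 fell in every type, against 132.8 and 78.7 if the types were independent. Another 2114 rose in 1 type and fell in another. Phase, calendar year and sampling date divided the libraries alike, with 0 dates shared, so phase could not be separated from them. The model also took the animals as independent, although they shared 9 study groups per phase and 25 dates in phase 1 or 23 in phase 2. Standard errors and p-values of the phase comparison do not allow for that clustering. They can be too small, and the counts of genes called too high. With marker levels of the other gates as covariates the number of genes called fell to 1426 in helper T, 3096 in cytotoxic T, 3979 in natural killer cells and 3618 in monocytes. With the level of the immediate early and NF-kB lists as a covariate it fell to between 347 (cytotoxic T) and 5017 (helper T), and the signs of RRAD in helper T and FOSB in natural killer cells turned.

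Most immediate early genes, transcribed within minutes of a stimulus, fell in phase 2 in each type. All 19 measured members fell in helper T cells (median log2 change -2.40, level lower in 41 of 44 animals). They were led by PPP1R15A, which reverses the stress-induced block of translation (-3.10 ± 0.18), and IER5 (-2.40 ± 0.15). All 20 fell in cytotoxic T cells (median -3.08, lower in 44 of 44 animals), led by EGR2 (-4.93 ± 0.20), NR4A2 (-4.15 ± 0.19) and NR4A3 (-6.27 ± 0.31). In natural killer cells 15 of 18 fell and 1 rose (median -2.33, 40 of 43 animals), with NR4A3 at -4.56 ± 0.28. In B cells 17 of 19 fell, or 18 adjusted over the list alone (median -1.43, 39 of 42 animals), with NR4A3 at -4.32 ± 0.23. Monocytes were mixed: 13 of 20 fell, among them FOSL1 (-3.74 ± 0.27), and FOS, JUNB, MYC and BTG2 rose (median -1.45, 38 of 43 animals). The list was called lower in each type by camera with the preset correlation, at adjusted p-values from 5.40e-10 to 0.00937. With an estimated correlation its adjusted p was 0.482 in both T cell types, 0.493 in natural killer and B cells and 0.7497 in monocytes. Beside these falls, monocyte markers in cytotoxic T libraries had a median change of -0.46 (6 of 12 fell), and B cell markers fell in monocyte libraries.

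Genes of NF-kB signalling and inflammation fell too, and in monocytes all 23 members did (median -3.20, lower in 43 of 43 animals). IL1A, a fever-inducing cytokine, changed by -8.40 ± 0.41, the neutrophil attractants CXCL2 and CXCL3 by -8.10 ± 0.38 and -8.53 ± 0.42 and CCL20 by -6.18 ± 0.42. In cytotoxic T cells 14 of 17 fell (median -1.29, 44 of 44 animals), with IL1B at -5.15 ± 0.24 and CD83 at -4.95 ± 0.17. In natural killer cells 10 of 14 fell (median -1.61, 42 of 43 animals), with CD83 at -4.70 ± 0.19. In helper T cells 12 of 17 fell and 3 rose (median -0.76, 43 of 44 animals). The NF-kB inhibitor NFKBIA changed by -3.20 ± 0.17 and TNFAIP3, another brake on the pathway, by -3.37 ± 0.20. In B cells 16 of 19 fell (median -1.64, 40 of 42 animals), while BIRC3 rose by 1.90 ± 0.11. The level of a list was the mean over the members tested in a type, scaled by TMM. With all listed genes and CPM by the library total, the immediate early level was lower in 39 of 44, 44 of 44, 40 of 43, 38 of 42 and 34 of 43 animals (helper T, cytotoxic T, natural killer, B, monocyte). The NF-kB level so taken was lower in 41 of 44, 44 of 44, 42 of 43, 40 of 42 and 43 of 43. Camera called the list in each type (adjusted p-values from 2.16e-10 to 0.00663). With an estimated correlation the adjusted p was 0.482 in monocytes, cytotoxic T and natural killer cells and 0.493 in helper T and B cells.

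**Figure D2:**
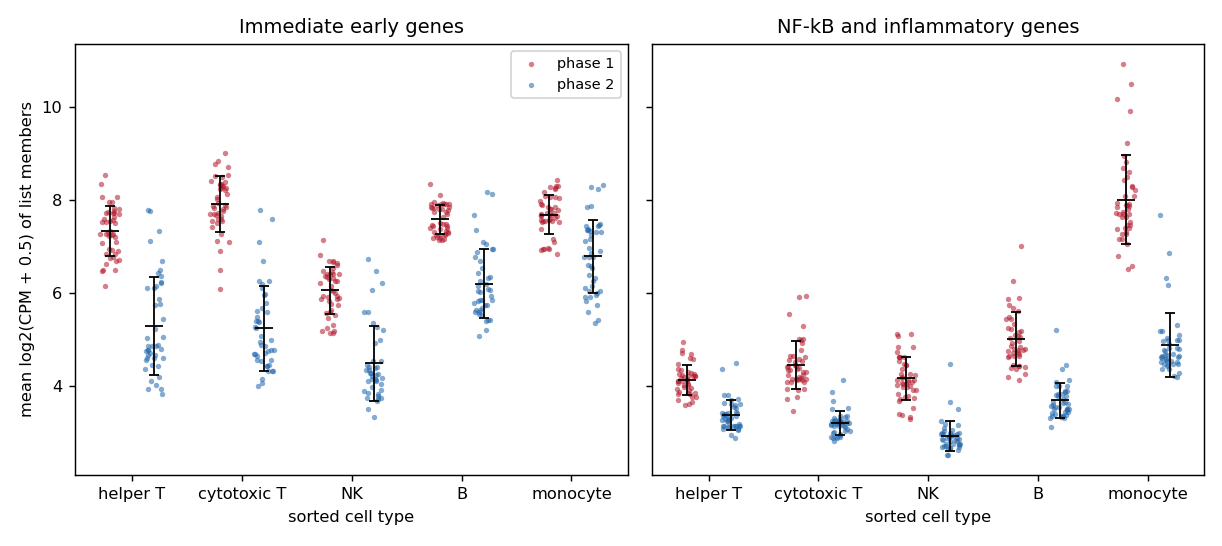
Mean log2 CPM by the library total of all listed immediate early and NF-kB genes, tested or not, in every library, by cell type and phase, points showing single libraries and black lines the mean and SD. The NF-kB level in monocytes averaged 8.01 in phase 1 and 4.87 in phase 2, and the immediate early level in cytotoxic T cells 7.91 and 5.24.

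Genes induced by glucocorticoids fell in all types: 16 of 17 in both T cell types (medians -1.75 in helper and -1.69 in cytotoxic T cells). In natural killer (-1.24) and B cells (-1.23) 15 of 17 fell and in monocytes 12 of 18 (-1.31). DDIT4, an inhibitor of mTOR signalling, changed by -2.50 ± 0.12 in helper T cells and -2.32 ± 0.12 in monocytes. The transcription factor KLF9 changed by -2.55 ± 0.13 and -4.16 ± 0.19 there, and the leucine zipper protein TSC22D3 by -1.75 ± 0.10 in helper T cells. The level was lower in 44 of 44, 44 of 44, 42 of 43, 40 of 42 and 43 of 43 animals, in the order helper T, cytotoxic T, natural killer, B and monocyte. Clock genes fell as well, 13 of 17 in each T cell type, 10 of 13 in natural killer cells, 10 of 14 in B cells and 11 of 14 in monocytes (12 adjusted over the list alone). Their level was lower in every animal of each type. PER1, a clock repressor that both lists hold, changed by -4.11 ± 0.22 in helper T, -4.02 ± 0.17 in cytotoxic T and -3.86 ± 0.20 in B cells. PER2 changed by -2.48 ± 0.13 in natural killer cells and NR1D2 by -2.44 ± 0.12 in monocytes. Both lists were called in each type by camera (the largest adjusted p-value was 0.00717 for the first and 0.0278 for the second). With an estimated correlation the adjusted p was 0.482 for both lists in each type.

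Ribosomal protein genes fell with few exceptions. In helper T cells 78 of 79 fell (79 adjusted over the list alone, median -1.01, lower in 43 of 44 animals) and in cytotoxic T cells 78 of 79 (-1.07, 41 of 44). The counts were 67 of 78 in natural killer cells (-0.66, 39 of 43), 76 of 78 in B cells (-0.57, 36 of 42) and 69 of 78 in monocytes (-1.03, 43 of 43). RPL39 changed by -2.13 ± 0.11 in helper and -2.21 ± 0.10 in cytotoxic T cells, and RPL35A by -1.61 ± 0.09 in natural killer cells and -2.05 ± 0.09 in monocytes. Camera called the list in each type (largest adjusted p-value 1.55e-10). The adjusted p with an estimated correlation was 0.493, 0.525, 0.617, 0.685 and 0.493 in helper T, cytotoxic T, natural killer, B cells and monocytes. Oxidative phosphorylation genes fell in T cells alone among the calls, 45 of 65 in helper T (median -0.47, 37 of 44 animals) and 45 of 65 in cytotoxic T cells (-0.41, 37 of 44). COX4I1 changed by -1.17 ± 0.09 in the first and ATP5G2 by -1.12 ± 0.09 in the second. With an estimated correlation the adjusted p was 0.777 and 0.811. Taken by the library total over all listed genes, the mean log2 level of the list was not lower in phase 2. It was 5.478 in phase 1 and 5.522 in phase 2 in helper T cells, and 5.487 and 5.527 in cytotoxic T cells. The fall of this list therefore depended on how its level was taken. In natural killer cells 20 rose and 26 fell of 64, in B cells 20 and 27 of 65 and in monocytes 15 and 35 of 65, without a call. Heat shock genes were called in helper T cells, where 14 of 19 fell (median -0.77, 38 of 44 animals; HSPA5 by -2.07 ± 0.09 and BAG3 by -1.96 ± 0.12), with an adjusted p of 0.596 once the correlation was estimated. By the library total over all listed genes the mean log2 heat shock level in helper T cells was 6.021 in phase 1 and 5.823 in phase 2. In the other types 12, 8, 11 and 6 of 19 fell (cytotoxic T, natural killer, B, monocyte) without a call.

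B cell markers moved apart between the gates. They rose in B cells themselves (13 of 17, 41 of 42 animals, CR2 by 2.33 ± 0.15 and SPIB by 1.70 ± 0.12). They rose in cytotoxic T libraries (11 of 13, median 1.35, 41 of 44 animals, MS4A1 by 1.93 ± 0.18) and fell in monocyte libraries (10 of 11, median -2.23, 39 of 43 animals, FCRLA by -4.30 ± 0.21 and CD22 by -2.23 ± 0.15). With an estimated correlation the adjusted p was 0.493 in B cells, 0.495 in cytotoxic T cells and 0.493 in monocytes. In helper T and natural killer libraries 9 of 13 and 4 of 4 rose without a call of the list. Over all 105 combinations of list and type, 31 were called with the preset correlation and 0 by camera with an estimated correlation, where 9 had an unadjusted p under 0.05. Fry called 83; it asks whether the members of a list move on balance in one direction and compares them with no other genes. Counts adjusted over the list alone differed from those over all genes in 9 combinations, by 1 gene each.

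The remaining lists were not called in any type, and most had members that passed the test in both directions. Of the interferon response genes 10 rose and 13 fell of 28 in helper T cells, and 11 and 13 of 28 in cytotoxic T cells. The counts were 12 and 12 of 28 in natural killer cells, 11 and 11 of 25 in B cells and 12 and 8 of 29 in monocytes. PARP9 rose in each type (1.44 ± 0.11, 1.64 ± 0.12, 1.26 ± 0.11, 1.49 ± 0.10 and 1.66 ± 0.13 in the same order), while ISG15, a ubiquitin-like protein, changed by -3.57 ± 0.25 in helper and -2.87 ± 0.19 in cytotoxic T cells. Among the receptors of chemokines and homing S1PR5, which guides lymphocytes out of tissue, rose by 1.45 ± 0.09 in natural killer cells. CXCR4, which holds cells in the marrow, changed by -3.09 ± 0.15 in cytotoxic T cells and -2.62 ± 0.14 in monocytes. CCR7, a lymph node homing receptor, changed by -5.74 ± 0.28 in monocytes. Of the receptors and homing genes 12 of 20, 11 of 20, 9 of 16, 9 of 16 and 6 of 14 rose and 6, 7, 1, 6 and 7 fell in the same order. Natural killer markers rose in 6 of 11, 5 of 13, 7 of 13, 5 of 11 and 5 of 11 cases, with TBX21, a transcription factor of cytotoxic cells, up by 1.96 ± 0.12 in natural killer cells. Cytotoxic granule genes were divided, with PRF1, perforin, up by 1.59 ± 0.11 and IFNG at -1.70 ± 0.22 in natural killer cells, where 7 of 14 rose and 5 fell. The counts were 5 and 4 of 14, 3 and 6 of 14, 2 and 4 of 10 and 1 and 6 of 9 in helper T, cytotoxic T, B cells and monocytes.

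T cell markers rose and fell in 7 and 5 of 14 cases in helper T, 8 and 4 of 14 in cytotoxic T, 8 and 1 of 11 in natural killer, 8 and 0 of 9 in B cells and 0 and 5 of 7 in monocytes. CD28, a costimulatory receptor, changed by -1.87 ± 0.13 in helper T cells and LCK, a T cell kinase, by 1.28 ± 0.14 in B libraries. Helper T markers rose in 6 and fell in 3 of 11 cases in helper T cells, where CTLA4 changed by -2.08 ± 0.16 and FOXP3 by 0.85 ± 0.11. They rose and fell in 4 and 3 of 8 cases in cytotoxic T, 2 and 0 of 3 in natural killer and 3 and 0 of 5 in B libraries. Cytotoxic T markers rose and fell in 4 and 4 of 10, 3 and 5 of 11, 6 and 2 of 11, 1 and 4 of 6 and 0 and 4 of 5 cases in helper T, cytotoxic T, natural killer, B cells and monocytes. Monocyte markers did in 4 and 2 of 11, 2 and 6 of 12, 0 and 3 of 8, 1 and 8 of 14 and 7 and 3 of 16, with CD14 up by 1.82 ± 0.21 and CSF1R by 2.01 ± 0.15 in monocytes. Cell cycle genes rose and fell in 9 and 11 of 27, 11 and 8 of 28, 10 and 7 of 27, 7 and 10 of 23 and 4 and 10 of 17 cases (CCNA2 up by 1.94 ± 0.13 in B cells). Class II presentation genes did in 7 and 5 of 15, 6 and 2 of 15, 4 and 6 of 11, 7 and 7 of 15 and 4 and 9 of 15, with CIITA, their master regulator, up by 2.60 ± 0.21 in monocytes. Plasma cell markers rose and fell in 3 and 1 of 6, 2 and 2 of 6, 1 and 1 of 4, 4 and 1 of 7 and 1 and 3 of 6 cases, with IGJ, the immunoglobulin J chain, up by 2.53 ± 0.18 in cytotoxic T cells. Platelet markers fell in 8 of 9 cases in monocytes (adjusted p = 0.213, PF4 by -1.26 ± 0.23) and in 1 of 5, 1 of 6, 2 of 6 and 2 of 5 in the other types. Neutrophil markers rose in 3 of 4, 3 of 4, 3 of 3, 1 of 4 and 2 of 6, led by the chemokine receptor CXCR2 (2.18 ± 0.20 in helper T cells). Dendritic cell markers fell in 4 of 6 cases in monocytes, the only type where enough were measured, and erythroid genes were too few to test. The median, the mean and the direction of the test disagreed in sign for 11 combinations, all of them uncalled, among them the interferon response in cytotoxic T, natural killer and B cells and monocytes.

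The third comparison asked whether the phase effect itself differed between cell types, and it did for 10510 of 11880 genes. ADORA2A, an adenosine receptor, rose by 1.19 ± 0.10 in helper T, 1.32 ± 0.09 in cytotoxic T and 0.74 ± 0.09 in natural killer cells, and its value in B cells was 0.05 ± 0.07 (adjusted p = 0.567). In monocytes it changed by -5.52 ± 0.28, from 126 ± 90.1 to 2.36 ± 1.83 CPM (n = 43; adjusted p for the difference between types 2.67e-127). SPATA13, a guanine nucleotide exchange factor, changed by -4.21 ± 0.18 in monocytes. It changed by between -0.54 and -0.20 in helper T, cytotoxic T and natural killer cells. Its value in B cells was -0.09 ± 0.07 (adjusted p = 0.188). ZFP36L2, which binds and destabilises messenger RNA, changed by -2.07 ± 0.11 in helper T and -1.64 ± 0.09 in cytotoxic T cells. It changed by 0.21 ± 0.08 in natural killer and -0.24 ± 0.10 in B cells and rose by 1.19 ± 0.12 in monocytes. SLC19A2, a thiamine transporter, changed by -3.07 ± 0.11 in monocytes and -1.62 ± 0.08 in B cells. BHLHE41, a clock repressor, rose by 0.97 ± 0.12 in B cells and changed by -4.48 ± 0.28 in monocytes. The largest adjusted p of the 5 genes was 3.02e-90.

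The fourth comparison asked whether the 9 study groups of a phase differed, with 2 genes named per phase and type. In phase 1, PRR12, a proline-rich nuclear protein, ranged in helper T cells from 77.9 ± 5.28 CPM in the lowest group to 291 ± 30.1 in the highest (n = 5 each, adjusted p = 2.07e-10), and ERH from 45.1 ± 4.96 to 186 ± 18.0 (1.16e-09). The zinc-finger genes ZNF33A (26.7 ± 3.42 to 84.7 ± 21.5 CPM) and ZNF248 (3.89 ± 0.388 to 18.5 ± 4.08) led in cytotoxic T cells. ZNF318 (9.38 ± 2.46 to 48.8 ± 7.11) and the kinase RPS6KA3 (109 ± 11.8 to 269 ± 56.8) led in natural killer cells. HIST1H1E, a linker histone, ranged from 5.33 ± 2.12 to 55.4 ± 5.32 CPM and ZNF460 from 49.8 ± 10.2 to 172 ± 11.7 in B cells. In monocytes HILPDA, a lipid droplet protein induced by hypoxia, ranged from 0.362 ± 0.259 to 55.6 ± 53.8 CPM. IL12B, an interleukin subunit, ranged from 0.466 ± 0.283 to 275 ± 567, where replicate 34 alone held 1288 CPM and the other 4 libraries at most 51.9.

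In phase 2 several leading genes rested on a single library of the highest group. CD8B in helper T cells (66.8 ± 143 CPM, n = 5) stood at 321.9 CPM in replicate 7 and at most 7.80 in the other 4 libraries. CD4 in cytotoxic T cells (90.3 ± 200 CPM) stood at 447.2 CPM in replicate 7 and at most 2.03 in the others. LTF, the neutrophil granule protein lactoferrin, stood at 276.0 CPM in helper T replicate 41 and at most 0.252 in the others of its group. MMP9, a gelatinase, stood at 344.2 CPM in monocyte replicate 18 and at most 7.55 in the other 3. VPS28, of the endosomal sorting machinery, ranged from 65.8 ± 11.5 to 125 ± 22.1 CPM in cytotoxic T cells. SMC2, of condensin, ranged from 17.9 ± 2.81 (n = 5) to 59.6 ± 17.2 (n = 3) and ATF3 from 2.23 ± 1.46 to 40.4 ± 55.6 in natural killer cells. In B cells ZNHIT6 ranged from 9.82 ± 3.80 to 29.9 ± 3.86 CPM (n = 4 each) and the endonuclease MUS81 from 79.1 ± 7.08 (n = 5) to 139 ± 8.88 (n = 4). In monocytes PTMA, prothymosin alpha, ranged from 286 ± 17.9 to 480 ± 57.1. The adjusted p-value of the 20 genes named over both phases was at most 0.00658.

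**Figure D3:**
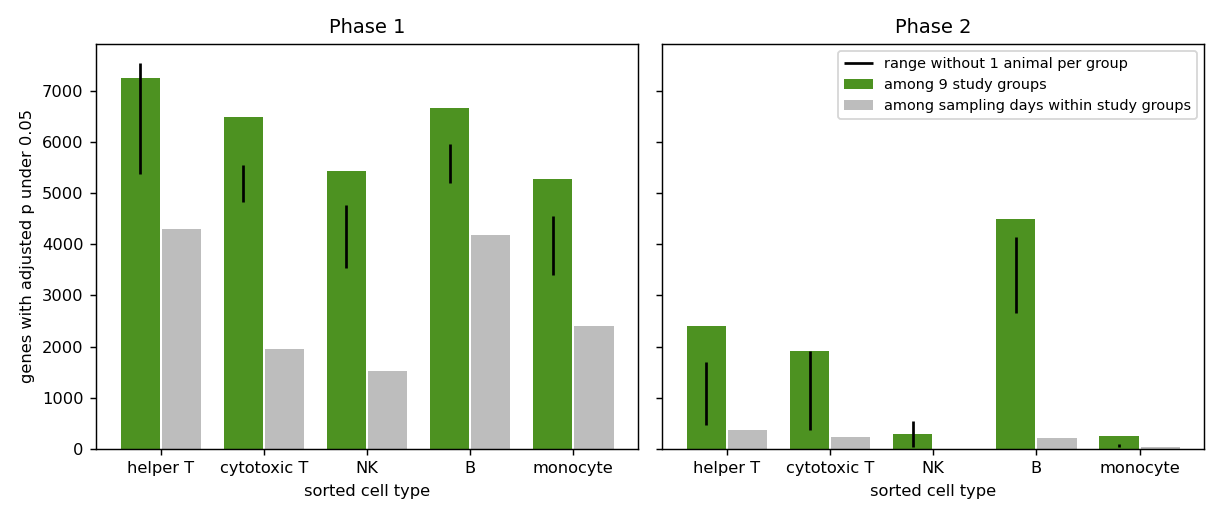
Genes that differed among the 9 study groups (green) and among sampling dates within study groups (grey), by cell type and phase, from edgeR. Lines give the range of the green counts when an animal of each group was left out, 32 to 540 for natural killer phase 2 against 298 with all animals.

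By edgeR 7247, 6492, 5428, 6671 and 5272 genes differed among the phase 1 groups in helper T, cytotoxic T, natural killer, B cells and monocytes, and 2410, 1907, 298, 4500 and 252 among those of phase 2. Whether the phases differed in this was not tested. In phase 1, 77 of 79, 77 of 79, 71 of 78, 75 of 79 and 73 of 79 ribosomal protein genes differed among groups in the same order, and 23 of 23 NF-kB genes did in monocytes. Adjusted over the list alone the counts were the same except for 75 in place of the 73. Of all genes tested, 66.3%, 57.8%, 54.2%, 62.2% and 54.0% differed among the phase 1 groups in that order. Among sampling dates within these groups 9 of 79, 0 of 79, 5 of 78, 66 of 79 and 0 of 79 ribosomal protein genes differed. For natural killer cells and monocytes of phase 2 limma-voom called 0 and 40 genes and DESeq2 1150 and 712. Leaving out an animal of each group moved the phase 2 counts of every type, to 475 to 1699 in helper T, 363 to 1922 in cytotoxic T, 32 to 540 in natural killer, 2648 to 4135 in B cells and 38 to 100 in monocytes. With the marker levels of other gates as covariates the count fell to 1842 and 663 in cytotoxic T cells of phases 1 and 2, to 2477 in natural killer cells and 2987 in monocytes of phase 1 and to 39 in monocytes of phase 2.

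Sampling date was a batch within the study groups, since 12 of the 18 groups shared no date with another and 4 dates held animals of 2 groups. With the study group held fixed, sampling dates separated 4298 genes in helper T, 1957 in cytotoxic T, 1517 in natural killer, 4178 in B cells and 2397 in monocytes in phase 1. In phase 2 the counts were 361, 223, 5, 202 and 30 by edgeR. Limma-voom called 0 in natural killer cells, where 774 genes had an unadjusted edgeR p under 0.05, and 0 in monocytes, where 1013 had. Study group and date can therefore not be told apart for most groups.

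The fifth comparison asked which genes kept their level in an animal across both samplings. C3, the central complement component, was named in all 5 types. Its log2 levels in the phases correlated across animals with r = 0.954 in helper T (rho = 0.934, n = 44) and 0.964 in cytotoxic T cells (0.955, n = 44). They did with 0.959 in natural killer (0.961, n = 43), 0.930 in B cells (0.936, n = 42) and 0.870 in monocytes (0.910, n = 43). The hedgehog receptor PTCH1 correlated with r = 0.943 in helper and 0.924 in cytotoxic T cells. The sodium channel SCN4A correlated with 0.921 in cytotoxic T and 0.948 in natural killer cells, and ALOX5AP, which leukotriene synthesis requires, with 0.942 in natural killer cells. In B cells SCRN1 gave r = 0.957 and TMEM178B 0.908. In monocytes the serine protease HTRA1 gave 0.874, MLKL, which carries out necroptosis, 0.881 and CSGALNACT1, of chondroitin sulfate synthesis, 0.739. Spearman's rho of the genes other than C3 lay between 0.5995 and 0.939. With C3 included, permutation p-values of r were 1e-05 in all cases, the smallest they can give (1.56e-05 adjusted over the 25 relations computed). Those of rho were at most 7e-05, and r without the 2 animals farthest from the median lay between 0.643 and 0.959. The named genes were picked as differing most among animals over both phases, which already favours agreement between the phases. Their p-values therefore give no independent test.

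Other genes held separate levels, and every animal was on the same side in both phases. CLEC12A, an inhibitory lectin receptor best known from myeloid cells, lay at up to 1.56 CPM in cytotoxic T cells of 18 animals and at no less than 22.4 CPM in the other 26. In helper T cells the levels were up to 2.59 and at least 5.66 CPM. MAMU-DOB, a class II chain that modulates peptide loading, lay at up to 8.46 CPM in helper T cells of 15 animals and at least 26.4 CPM in 29. CORO2A, a coronin, lay at up to 13.7 CPM in natural killer cells of 22 animals and at least 26.1 CPM in 21. HSPA4L, a heat shock protein, lay at up to 2.72 CPM in B cells of 17 animals and at least 8.48 CPM in 25. No pooled correlation is given for these. Within the animals of the higher level r for CLEC12A was 0.714 (rho = 0.722, n = 26, permutation p = 5e-05) in cytotoxic T cells and 0.857 (rho = 0.847, n = 26) in helper T cells. It was 0.483 (rho = 0.330, n = 29, p = 0.00786 and 0.0809) for MAMU-DOB and 0.356 (rho = 0.316, n = 21, p = 0.114 and 0.165) for CORO2A. It was 0.610 (rho = 0.424, n = 25, p = 0.00121 and 0.0344) for HSPA4L. Among the animals of the lower level no r passed the test (0.419 with p = 0.0825 for CLEC12A in cytotoxic T cells, n = 18).

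**Figure D4:**
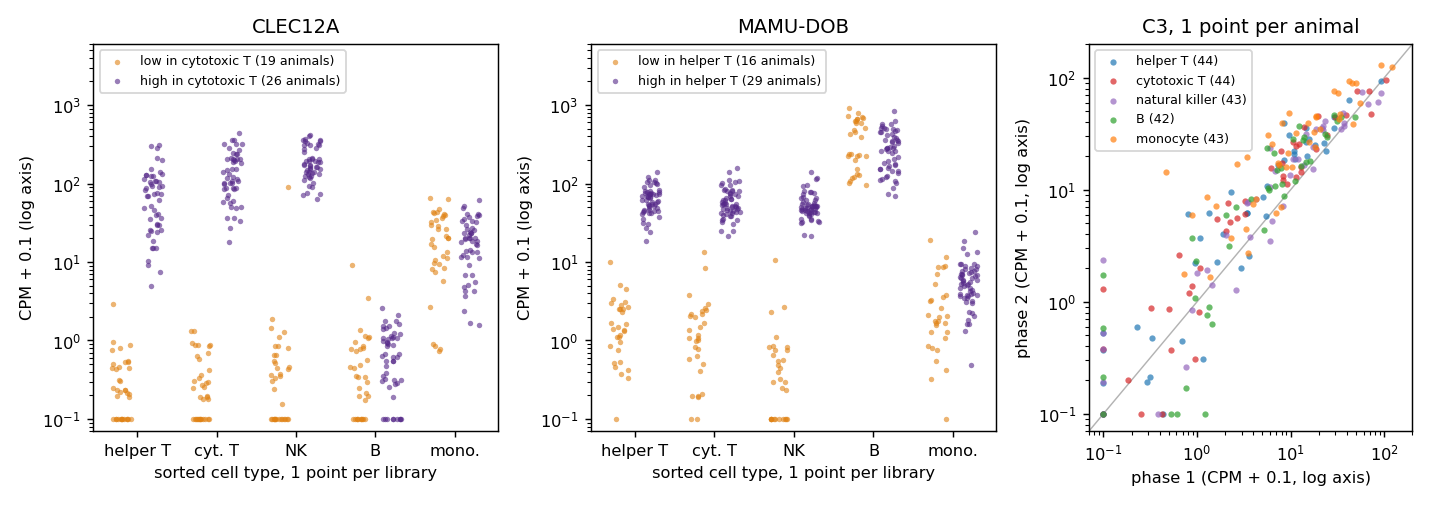
CLEC12A and MAMU-DOB in every library (CPM, log axis), by cell type and by the level of the animal in the type that parts the animals, and C3 in phase 1 against phase 2, each point a library or an animal. CLEC12A in cytotoxic T cells lay at up to 1.23 CPM in the libraries of 19 animals and at 17.7 CPM or more in those of the other 26.

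By edgeR 2172 of 10443 genes differed among animals in helper T, 1761 of 10541 in cytotoxic T, 1434 of 9706 in natural killer, 1576 of 10265 in B cells and 666 of 9809 in monocytes. Of these, 111 of the 8817 genes tested in all 5 types did so in each, against 0.068 if the types were independent. The median r between phases of the called genes lay between 0.425 (B cells) and 0.459 (natural killer cells). Among the 111 genes the mean r over the types ran from 0.084 (LCN2) to 0.935 (C3). A call therefore did not show that a gene kept its level closely. In helper T libraries 11 of 11 natural killer markers, 10 of 10 cytotoxic T markers and 13 of 14 granule genes differed among animals. Their median r between phases was 0.66, 0.76 and 0.72. Markers of other cells differed there too, 12 of 13 B cell, 8 of 11 monocyte and 4 of 4 neutrophil markers (median r 0.48, 0.15 and 0.38). Of the T cell markers 1 of 14 did and of the helper T markers 4 of 11. Of the ribosomal protein genes 1 of 79 differed and of the immediate early genes 3 of 19; no test compared the lists. Whole profiles kept the animal too. The correlation across genes of deviations from the phase mean was higher within than between animals. The difference was 0.274 in helper T (43 of 44 animals above the mean with other animals), 0.250 in cytotoxic T (42 of 44), 0.262 in natural killer (42 of 43), 0.218 in B cells (39 of 42) and 0.160 in monocytes (42 of 43), each with a permutation p of 1e-05, the smallest possible. Among the phase 2 libraries, that of the same animal lay closest to the phase 1 library for 30 of 44, 29 of 44, 29 of 43, 23 of 42 and 18 of 43 animals, where chance gives 1. The count of monocyte genes fell to 341 with limma-voom and to 393 with the study groups as covariates. That of natural killer cells rose to 2347 with no filter on low counts and to 2198 with the marker levels of other gates as covariates.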

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

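The tests of library depth, of cells from other gates, of exchanged labels, of the animal's identity over the other cell types and of sequence variants were chosen only after the result was seen. In the study groups with the highest and the lowest mean of each named gene, single libraries were compared with their group. In 5 of 39 groups, all of them those with the highest mean, a library stood far from the others by Dixon's test. Chance gives that in about 1 of 20 groups not picked for their mean, and a single high library itself raises a mean, so the rate does not apply to these groups. CD8B in helper T phase 2 stood at 321.9 CPM in replicate 7 against 0.655 to 7.80 in the other 4 libraries, and CD4 in cytotoxic T phase 2 at 447.2 CPM in replicate 7 against 0 to 2.03. LTF in helper T phase 2 stood at 276.0 CPM in replicate 41 against 0 to 0.252 in the other 4. IL12B in monocyte phase 1 stood at 1288 CPM in replicate 34 against 0 to 51.9 in the other 4. MMP9 in monocyte phase 2 stood at 344.2 CPM in replicate 18 against 1.79 to 7.55 in the other 3.

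The effect of phase differed between the cell types for 10510 genes by a joint test of the difference. The adjusted p was 2.67e-127 for ADORA2A, 1.11e-114 for SPATA13, 1.21e-93 for ZFP36L2, 4.06e-92 for SLC19A2 and 3.02e-90 for BHLHE41.

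Most immediate early and NF-kB genes measured were lower in phase 2 in each cell type, though 4 of 20 immediate early genes rose in monocytes and 3 of 17 and 3 of 19 NF-kB genes in helper T and B cells, and with an estimated correlation camera called neither list in any type (smallest adjusted p 0.4823). Library depth as the whole cause was argued against: with each animal's pair of libraries thinned to the lower total, at least 86.2% of the median change of either list was left in every type. Fewer cells of another gate were argued against as the whole cause in cytotoxic T libraries, where the marker list that fell most had a median of -0.4632 against -3.08 for the immediate early list, and in monocyte libraries, where the NF-kB median was still -2.29 with the other-gate marker levels as covariates and 21 of 23 members fell. With the same covariates the immediate early median was -1.72 in cytotoxic T libraries (14 of 20 fell) and -1.61 in helper T libraries (10 of 19), and 5 of 17 NF-kB members fell in helper T libraries, so other gates stay open as a part of the change. Handling of the blood that differed between sampling days cannot be told apart from phase, because the phases shared 0 dates (within phase 1 study groups 44.2% of the members of both lists differed among dates against 27.1% of all genes as means over types, but 40% against 39.3% in helper T and 38.1% against 38.96% in B cells), and social or seasonal differences between the phases stay open and untested.

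The T cell libraries of the phase 2 draw of replicate 7 held genes of the other T gate. An exchange of labels alone was argued against. The library labelled cytotoxic T held CD8B at 81.4% of the median of the other cytotoxic T libraries. An exchange together with cytotoxic T cells in that library stays open. The library labelled helper T held CD4 at 1.86 CPM, unscaled, and lay nearer to the median cytotoxic T profile than to its own (r 0.951 against 0.900). A mixture of both T cell types in the library labelled cytotoxic T would bring shares adding up to about 100%. The shares of helper T genes (32.2%) and of cytotoxic T genes (66.7%) added up to 98.96%, but the other 86 T cell libraries of phase 2 gave 56.7% to 176%. CD4 alone stood at 74.7% of the helper T median beside the 81.4% of CD8B, more than a mixture of cells at these medians would give. Single libraries spread widely around such medians (CD8B from 75.3 to 697 CPM, unscaled, over the cytotoxic T libraries of both phases). A mixture is therefore left open. A library of another animal in place of the one labelled helper T was argued against, since its correlation with the other cell types of its own animal exceeded the highest with another animal by 0.1713 (0.354 against 0.1827), where 88 of the 88 other helper T libraries also matched their own animal; an earlier test with the phase 1 cytotoxic T libraries alone gave 0.340 against 0.335 and decided nothing. The genes compared over the other cell types were picked with the same animal labels, the doubted library among them. Libraries of the same draw were included, so effects shared by a draw can add to that match. No biological explanation was tested.

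CLEC12A, MAMU-DOB, CORO2A and HSPA4L lay at 1 of 2 separate levels in each animal in some cell types. Sequence variants that keep reads from being counted would lower a gene in all types of an animal. That was argued against for CLEC12A, MAMU-DOB and CORO2A. Within another type, low and high animals overlapped where a loss of reads would part them (ranges in unscaled CPM). CLEC12A in monocytes ran from 0.641 to 65.8 in low and from 1.47 to 61.9 in high animals. MAMU-DOB in B cells ran from 94.4 to 913 and from 68.6 to 841. CORO2A in helper T cells ran from 12.3 to 92.8 and from 11.8 to 96.3. The share above a ceiling, given next, can be high through higher expression in that type alone. At least 89.2% of the libraries of another type of the low animals lay above the highest level of the type that parts the animals: 33 of 37 monocyte libraries for CLEC12A, 31 of 31 B cell libraries for MAMU-DOB and 44 of 45 helper T libraries for CORO2A. For HSPA4L the share was at most 22.2%, so such variants cannot be excluded there; a regulatory variant acting in some cell types is a hypothesis for the other 3 that no table tested.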

How the results depend on the processing

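The covariate of immediate early and NF-kB level, the thinning and the sets without doubted or shallow libraries were tests added after the data had been seen. In the phase comparison 108 alternative counts stayed within 1.5 times of the reported one and 9 did not; of the named genes 913 alternative values kept their direction and call, 6 kept their direction without the call and 2 turned. With other-gate markers as covariates beside the replicate block 1426 helper T, 3096 cytotoxic T, 3979 natural killer and 3618 monocyte genes were called, and with the level of both lists 5017, 347, 1589, 3660 and 4211 (helper T, cytotoxic T, natural killer, B, monocyte), where the log2 change of RRAD in helper T turned to 0.67 and of FOSB in natural killer cells, itself a list member, to 0.27; the cause was not tested. Leaving out the replicate block changed no other call of a count. The planned fit of limma to the authors' residuals for phase was not run, since their centring removes the phase effect. Lists called in a type numbered 0 in each with an estimated correlation and 13, 17, 18, 18 and 17 with fry. A minimum of 2 on the log2 scale gave 236, 1126, 1714, 2768, 764, 1717, 2699, 1795, 2655 and 2377 genes for the 10 pairs of types (helper T against cytotoxic T, natural killer, B and monocyte first) and 42, 15, 75, 312 and 780 high in a type, by its own construction; with no low-count filter 110 were high in cytotoxic T cells; 90 other counts of pairs and 44 of genes high in a type stayed. Same-animal correlations stayed in 25 of 25 alternatives and the difference of the phase effect in 3 of 3.

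Among study groups 82 alternative counts stayed and 35 did not. Other-gate covariates gave 1842 and 663 genes in cytotoxic T phases 1 and 2, 2477 in natural killer phase 1, and 2987 and 39 in monocyte phases 1 and 2. The log10 total as covariate gave 789 in natural killer, 2344 in B and 53 in monocyte phase 2; limma-voom gave 0 in natural killer and 40 in monocyte phase 2, and DESeq2 1150 and 712. Leaving out an animal of each group in turn gave 475 to 1699 in helper T, 363 to 1922 in cytotoxic T, 32 to 540 in natural killer, 2648 to 4135 in B and 38 to 100 in monocyte phase 2, and 3528 to 4765 in natural killer and 3405 to 4558 in monocyte phase 1; these sets held fewer animals. For sampling dates limma-voom gave 954 in natural killer and 1321 in monocyte phase 1 and 125, 0 and 0 in cytotoxic T, natural killer and monocyte phase 2, and for the other phase's study group 0 throughout. Genes that differed among animals numbered 2347 in natural killer cells with no low-count filter and 2198 with other-gate covariates, and 341 in monocytes with limma-voom and 393 with the study groups as covariates; the cause was not tested. Median totals were lowest in natural killer cells and monocytes of phase 1, at 3349357 and 2960553 reads.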

Other observations

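The tests of sampling dates, of shared draw levels and of the genes near 0 in phase 2 were planned or written before their result was seen, and the only splits chosen after were those of helper T cells for phase and, in phase 1, for both kinds of study group, and those by whole dates, added once the other splits had been seen. Immediate early levels went along with each other between the cell types of a draw on average, though not in every pair of types. With study group means removed, the level of the list correlated between cell types of the same draw with a mean r of 0.3119 in phase 1 (rho = 0.267, n = 44 animals) and 0.688 in phase 2 (rho = 0.656, n = 38). Single pairs of types ran from -0.0858 to 0.590 in phase 1 and from 0.563 to 0.809 in phase 2. The permutation p was 1e-05 for both r, the smallest it can give, and 2e-05 and 1e-05 for rho; without the 2 farthest animals r was 0.254 and 0.594. A state shared by the whole blood draw was a hypothesis written before the test, and the means are consistent with it; whether it arose in the animal or in handling was not tested.

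GJB1, C1QL2, NKX6-1, CXCL6, SLC26A9, MMP10, LIPG, APOC1 and PTCHD2 were counted in phase 1 and near 0 in every cell type in phase 2, and are named for that and not by the fixed rule. Each had at least 1 read in a phase 2 library, and 0 genes showed the reverse. The hypothesis of an activated state of the cells in phase 1 was tested across phase 1 libraries with study group means removed. The median correlation of these genes with the level of the immediate early and NF-kB lists was 0.1414, above 97.91% of 10000 random sets of genes (median of the random sets -0.0352). The correlation was small, and 3 of the 9 genes correlated slightly negatively (GJB1 -0.04999, C1QL2 -0.0928 and APOC1 -0.0321). For these 3 the test gave no support to the hypothesis, and values this near 0 do not exclude it either.

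The study group of the other phase left little trace. In phase 1 edgeR called 0, 3, 0, 0 and 8 genes by the later group and in phase 2 it called 3, 9, 7, 65 and 4 by the earlier group, in the order helper T, cytotoxic T, natural killer, B and monocyte. Limma-voom called 0 in all 10 cases, where edgeR gave 483, 508, 431, 395 and 570 genes an unadjusted p under 0.05 in phase 1 and 363, 448, 346, 879 and 529 in phase 2.

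Across cell types, 438 of 440 libraries correlated better with the libraries of their own animal than with those of any other (mean r 0.494 against 0.222 for the highest other animal). The genes, up to 150 per pair of types, were picked as differing among animals in both types with the same labels and libraries. Libraries of the same draw were included, so effects shared by a draw can raise the match. The exceptions were monocyte phase 1 replicates 12 and 35. NCAM1, named outside the fixed rule as a natural killer marker in humans, stood at 258 CPM in monocytes and 6.98 CPM in natural killer cells.

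Other splits of the same libraries, fitted by limma-voom, were compared with the real ones. With phase labels exchanged within animals, chance can be excluded in each type (1 of 100 splits as large): 8475, 8632, 7581, 8312 and 8081 genes in the order above against at most 4416, 4854, 2597, 5066 and 2606. With the 18 study groups split 9 against 9 it can be excluded too (8225, 8395, 7375, 8183 and 8080 against at most 7514, 7626, 6361, 7261 and 7175). What the other splits with high counts shared was not tested. With single animals shuffled among the study groups of phase 1, which breaks up sampling dates, a chance placing of single animals can be excluded (6742, 6023, 5130, 5993 and 4029 against at most 1110, 153, 1122, 1 and 28). The same held in phase 2 for helper T (2012 against 264), cytotoxic T (1649 against 98), B cells (3261 against 944) and monocytes (40 against 1). A chance placing of whole dates is not addressed by these splits. For natural killer phase 2 these splits decide nothing, because the real count was 0 and all 100 of 100 splits were as large by construction (highest other 3).

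With whole dates moved between study groups of the same size, other splits called far more. In phase 1 chance can still be excluded (1 of 100 splits as large), with highest others of 6167, 4554, 3459, 4228 and 3677 for the same real counts. In phase 2 it can be excluded for B cells (1 of 100, highest other 2218). For monocytes 2 of 100 splits were as large (highest other 106) and for helper T cells 4 of 100 (highest other 3799). These shares are not adjusted over the cell types and phases tested, so chance is not firmly excluded for either type. It cannot be excluded for cytotoxic T cells of phase 2, where 6 of 100 splits called at least the real 1649 (highest other 3217), and natural killer phase 2 is left undecided by its real count of 0 (100 of 100, 972). These splits keep dates whole but do not part study groups from dates.

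For the study group of the other phase the splits decide nothing either, since all real counts were 0 and every split was as large by construction. The highest others were 18, 18, 148, 54 and 112 in phase 1 and 8, 1, 2053, 16 and 2 in phase 2. A count of 2053 goes with some structure among the natural killer samples, and which one was not tested. For animals chance can be excluded (1813, 1602, 1306, 1360 and 341 against at most 6, 21, 79, 45 and 28). For cell types it can be excluded in each pair (963, 2573, 3243, 5313, 1870, 3265, 5234, 3369, 5026 and 4761 genes, with the highest other split at most 24), for genes high in a type (191, 59, 256, 615 and 1383 against 0) and for the difference of the phase effect between types (11117 against 14), with 1 of 30 splits as large.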
